A study of Homo sapiens with 12 samples.

How the data were processed

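Gene expression was measured in spheroids of HepG2, a human hepatocellular carcinoma cell line, that were 10 days old per the labels. The 12 arrays fall into 3 groups of 4: wild type, HIF-1α knockdown and HIF-2α knockdown. HIF-1α, encoded by HIF1A, and HIF-2α, encoded by EPAS1, are the oxygen-regulated subunits of the hypoxia-inducible transcription factors. Per the labels' protocols, spheroids were grown in stirred flasks and total RNA was isolated with a column kit. RNA was amplified with a kit applied to 250 microdissected cells, labelled with biotin and processed with an Affymetrix wash and stain kit. The series' design text gives 4 different spheroid experiments per genotype, so the arrays of a group stand for different spheroid cultures of cells of that genotype. How the genes were knocked down, whether the wild type cells carried a control construct, and which part of the spheroid the cells came from are not given in the sources used here.

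The values used are the authors' deposited log2 values, 1 table of 32321 probe sets by 12 arrays; the base of the logarithm was inferred from their range, 5.94 to 15.1. The background correction, summarization and normalization behind them are not given in the sources used here. The medians of the arrays lie between 7.29 and 7.41, but the distributions of their probe set values are not identical. The interquartile range ran from 1.70 in wild type replicate 2 to 2.04 in HIF-1α knockdown replicate 3. The highest value lay between 13.85 and 14.14 on the HIF-1α knockdown arrays and between 14.24 and 14.97 on the wild type arrays. In HIF-2α knockdown it lay between 13.92 and 15.05. Close medians thus do not put the whole range of values on a common scale. A quantile normalization made before summarization need not leave the distributions identical, so whether one was made cannot be told. The values carry no counts or detection calls, so a level near the floor cannot be told from no signal, and the number of arrays limits the precision. The smallest root mean square difference between 2 arrays was 0.137, so no array was a copy of another.

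Probe sets were named from the platform annotation, with symbols brought up to date through Entrez identifiers in a RefSeq table of assembly GRCh38.p14, from which names were taken and no positions. Of the probe sets, 19158 had 1 gene symbol, 1388 had several and 11775 had none in that annotation. Of the 19158 symbols, 19128 matched through the identifier, 4 by the symbol itself and 26 were kept as given. Only probe sets with 1 symbol were used, and for the 637 genes with more than 1 such probe set the brightest over all arrays stood for the gene, which left 18404 genes.

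Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit on 1 mean per group over all 12 arrays and eBayes, so that the 3 groups share 1 estimate of the spread. Adjusted p is the Benjamini-Hochberg value over the 18404 genes within a comparison, and a gene is called changed when it lies below 0.05. No gene was removed for a low level and no fold threshold was applied. Fold changes are differences of mean log2 values, and SE is limma's moderated standard error. The p-values measure the spread between these arrays. For HIF1A, EPAS1 and the mean of each list per array a two-sided exact permutation test of the 4 against 4 arrays was added, and 0.0286 is the smallest p it can give.

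Before the data were examined, the groups, the tests, the other settings to be run, 39 gene lists and the rule for named genes were fixed. The rule names HIF1A and EPAS1 in every comparison. It adds the 12 largest rises and 12 largest falls among changed genes for which every array of a group lies above every array of the other, and up to 4 members of a list with the smallest p. It also adds up to 8 genes changed in the same direction in both knockdowns and up to 8 changed in opposite directions, by the smallest p. Genes outside the rule are named as chosen after their values were seen. Of the 1227 symbols in the lists, 1108 genes were measured, and the others were not analysed here. Each list was compared with all other genes by camera, part of limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated from the arrays, and camera on ranks, were run beside it, as was fry, which tests a list against no change and not against other genes.

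The script was tested on simulated values with the means and spreads of the 18404 genes and 50 genes changed by each known fold. In the simulated comparison of HIF-1α knockdown with wild type it recovered 48% of genes changed by 1.25-fold, 96% by 1.5-fold and 100% by 2-fold. For HIF-2α knockdown against wild type the shares were 60%, 86% and 98%, and for the knockdowns against each other 44%, 82% and 100%. Unchanged genes called were 6, 13 and 6 in these comparisons. The simulated noise was independent between genes and held no differences between whole arrays, so these shares need not hold for the real arrays. Alternatives covered quantile normalization, centring of each array, a filter on dim genes, the summary of several probe sets, the groups in the fit, blocks for the replicate number, other variance models, stricter thresholds and leaving out each array. Fits without 3 arrays that have a raised floor, and with the ribosomal protein level as a covariate, were added after the values of the arrays had been seen.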

Results

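The deposited table holds 12 arrays of HepG2 tumour spheroids, 4 each of wild type, HIF-1α knockdown and HIF-2α knockdown, and the groups were compared with each other. Values are on the log2 scale, with n = 4 arrays per group throughout. Any 2 arrays correlated across probe sets at r between 0.984 and 0.996. HIF-2α knockdown replicate 2 stood apart on the first principal component, the axis of largest variation between arrays (24.3% of the variance). It lay at 25.3 there, against -11.8 to 3.26 for the other arrays. Wild type replicates 1 and 2 and HIF-2α knockdown replicate 4 had a raised floor, with the 0.1 percentile of their values at 6.34, 6.33 and 6.35 against 6.11 to 6.23 on the other arrays.

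Each targeted transcript was lower in its own knockdown and in no array overlapped with wild type. HIF1A had a mean log2 value of 10.70 in wild type and 9.46 in HIF-1α knockdown, so 42.5% of the wild type signal remained (log2 fold change -1.23, SE 0.15, adjusted p = 0.00241, exact permutation p = 0.0286). EPAS1 had a mean of 11.01 in wild type and 9.89 in HIF-2α knockdown, with 46.0% remaining (log2 fold change -1.12, SE 0.09, adjusted p = 0.000206, exact permutation p = 0.0286). The other transcript was not called in either knockdown: HIF1A differed by 0.24 in HIF-2α knockdown (SE 0.15, adjusted p = 0.587) and EPAS1 by -0.03 in HIF-1α knockdown (SE 0.09, adjusted p = 0.938). The array values ran from 10.62 to 10.79 for HIF1A in wild type and from 9.25 to 9.64 in HIF-1α knockdown. For EPAS1 they ran from 10.83 to 11.26 in wild type and from 9.67 to 10.02 in HIF-2α knockdown. Without the 3 arrays with a raised floor, which leaves 2 wild type arrays, the HIF1A difference was -1.24 with an adjusted p of 0.103.

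**Figure D1:**
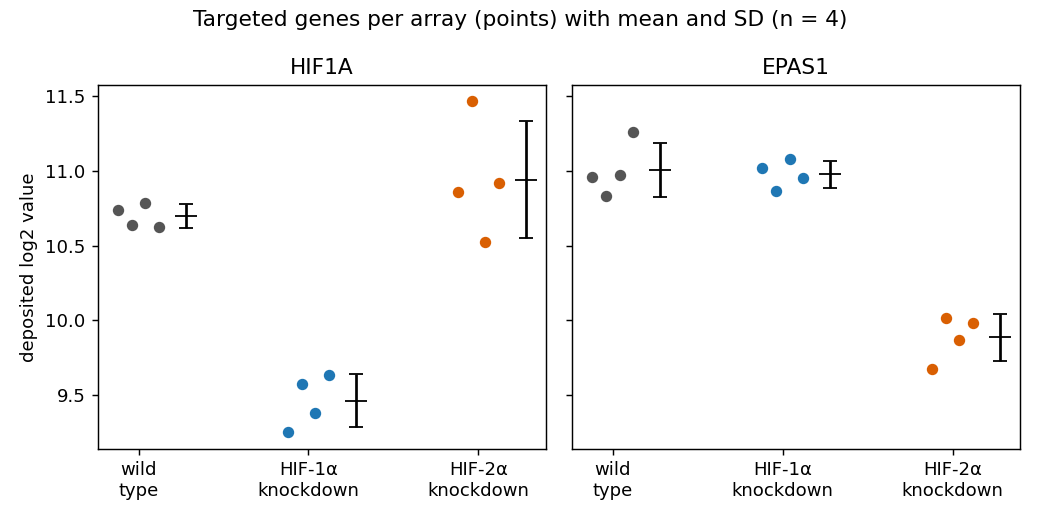
Deposited log2 values of HIF1A and EPAS1 on each array (points), with the mean and SD of the 4 arrays of each group (bars), for wild type, HIF-1α knockdown and HIF-2α knockdown. HIF1A lies at 9.25 to 9.64 in HIF-1α knockdown and EPAS1 at 9.67 to 10.02 in HIF-2α knockdown, below all wild type arrays.

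The comparison of HIF-1α knockdown with wild type asked which transcripts differ when HIF1A is reduced. The 3 genes of the fibrinogen chains, the clotting protein made by hepatocytes, fell: FGB was 3.36-fold lower (log2 fold change -1.75, SE 0.11, adjusted p = 9.03e-06), FGA 2.32-fold lower (SE 0.12, adjusted p = 0.000339) and FGG lower by 0.68 on the log2 scale (SE 0.12, adjusted p = 0.0207). ENO1, the glycolytic enolase, was 1.70-fold lower (SE 0.14) and SLC2A3, a glucose transporter, 1.57-fold lower (SE 0.14). Most members of the glycolysis list, described below, did not pass. Among the rises, TACC1, which encodes a microtubule-associated coiled-coil protein, was 2.47-fold higher (SE 0.11, adjusted p = 0.000123), and SPARC, a matricellular protein, was 2.18-fold higher (SE 0.17, adjusted p = 0.00763).

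Further large falls were seen for LRRTM4, a leucine-rich repeat membrane protein (2.10-fold), ALCAM, a cell adhesion molecule (2.04-fold), SPTSSB, a small subunit of serine palmitoyltransferase (1.88-fold), and SLC19A3, a thiamine transporter (1.77-fold). RPL11, a protein of the large ribosomal subunit, fell 1.72-fold and ARFGEF3 1.57-fold. MXRA7 was 2.45-fold higher, the histone gene H2BC12 2.27-fold, the glutathione transferase GSTA1 2.13-fold, the tetraspanin TSPAN7 2.04-fold and the fatty acid desaturase FADS2 1.92-fold. CCDC59 was 1.79-fold higher, RCN1, a calcium-binding protein of the endoplasmic reticulum, 1.79-fold, SH3BGRL 1.74-fold, the sulfotransferase SULT1C2 1.73-fold and the transcription factor KLF7 1.73-fold. The adjusted p of these genes lay between 0.000116 for LRRTM4 and 0.0368 for RPL11. In all, 177 of 18404 genes were called by limma, 150 higher and 27 lower, with 6 at least 2-fold higher and 5 at least 2-fold lower. After quantile normalization the calls were 140 higher and 114 lower, while with each array centred on its median they were 67 higher and 18 lower. The split between rises and falls thus depended on the kind of scaling. Without the 3 arrays with a raised floor 22 genes were called, 8 higher and 14 lower. Leaving out single arrays gave from 50 genes without HIF-1α knockdown replicate 3 to 483 without wild type replicate 3.

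By camera, 7 of the 39 lists were shifted in HIF-1α knockdown, and no call held with an estimated correlation (adjusted p from 0.765 to 0.900 for these lists). The glycolysis list was lower. Of 22 measured members 4 fell, none rose and 18 did not pass, and 12 fell when adjusted over the list alone (median -0.28, camera adjusted p = 2.13e-10; adjusted p = 0.765 with an estimated correlation). The 4 were ENO1, SLC2A3, HK2, the hexokinase that opens glycolysis (log2 fold change -0.48, SE 0.08), and GPI, glucose phosphate isomerase (-0.52, SE 0.11). After quantile normalization 9 glycolysis genes passed as lower, with a smaller list median of -0.175 (camera adjusted p = 1.28e-07). Without the 3 arrays with a raised floor, with fewer arrays in the fit, 0 did, while the list median was -0.37 (camera adjusted p = 2.47e-11). Of 42 hypoxia-induced HIF targets HK2 alone fell, and 8 fell when adjusted over the list alone (median -0.09, camera adjusted p = 5.32e-06; adjusted p = 0.865 with an estimated correlation). The number of these targets that fell was 6 after quantile normalization and 0 without the raised-floor arrays, where their median was -0.21 (camera adjusted p = 3.26e-09). Of 49 hepatocyte secreted proteins the 3 fibrinogen genes fell and none rose, with 5 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000154; adjusted p = 0.900 with an estimated correlation). Their median was -0.14, and -0.03 after quantile normalization (camera adjusted p = 0.538). The array means of the secreted protein list gave an exact permutation p of 0.0857.

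The ribosomal protein list, fixed as a marker of RNA amplification, had the largest shift. Of 39 measured members 38 were negative, RPL11 fell, and 24 fell when adjusted over the list alone (median -0.43, camera adjusted p = 2.81e-22; adjusted p = 0.865 with an estimated correlation). With quantile normalization 4 fell and the median was -0.20 (camera adjusted p = 1.28e-07), and 0 fell without the raised-floor arrays, where the median was -0.54 (camera adjusted p = 5.51e-24). That last fit keeps wild type replicates 3 and 4, with list means of 12.44 and 12.03. The larger shift there thus leans on replicate 3, which has the highest mean of all arrays. Camera with an estimated correlation was not run in that fit. The mean of the list per array ran from 11.90 to 12.44 in wild type and from 11.61 to 11.93 in HIF-1α knockdown, an overlap of the groups (exact permutation p = 0.0571). This difference between arrays stands beside the shifts of the glycolysis and secreted protein lists above. The replication-dependent histones, a marker for the capture of RNA without poly(A) tails, had 31 of 38 members negative (camera adjusted p = 0.00421; adjusted p = 0.900 with an estimated correlation). The histone median was -0.08, and -0.04 after quantile normalization (camera adjusted p = 0.101) and -0.13 without the raised-floor arrays (camera adjusted p = 3.21e-05). H2BC12 was the 1 member that rose and none fell, and adjusted over the list alone 2 rose and 3 fell. Oxidative phosphorylation genes were lower by a median of 0.06, with COX5A, a cytochrome oxidase subunit, the 1 of 56 that fell and 2 falling when adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.900 with an estimated correlation, and 0.125 after centring each array). Without the raised-floor arrays their median was -0.20 (camera adjusted p = 1.2e-09). With all arrays, the array means of the oxidative phosphorylation list did not separate the groups (exact permutation p = 0.629). Among 28 p53 targets TNFRSF10B, a death receptor, rose (log2 fold change 0.29, SE 0.06) and 7 rose when adjusted over the list alone (camera adjusted p = 0.0034; adjusted p = 0.865 with an estimated correlation). The p53 target median was 0.07, and 0.04 after quantile normalization (camera adjusted p = 0.288) and 0.03 without the raised-floor arrays (camera adjusted p = 0.146). With all arrays, the array means gave an exact permutation p of 0.4 for the histones and 0.0286 for the p53 targets, not adjusted for the number of lists.

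The comparison of HIF-2α knockdown with wild type asked the same of EPAS1. IGFBP1, a hepatocyte secreted protein that binds insulin-like growth factors, had the largest fall, 6.62-fold (log2 fold change -2.73, SE 0.27, adjusted p = 0.000349). CP, which encodes the copper-carrying ferroxidase ceruloplasmin, fell 3.64-fold (SE 0.18, adjusted p = 0.000324) and CHST15, a chondroitin sulfate sulfotransferase, 2.87-fold (SE 0.14, adjusted p = 0.000324). Some genes known to be induced by hypoxia fell as well. NDRG1 was 2.25-fold lower (SE 0.12), the transcription factor BHLHE40 2.04-fold lower (SE 0.13) and LOX, the collagen cross-linking lysyl oxidase, 2.03-fold lower (SE 0.17). Most members of the list of hypoxia-induced targets, described below, did not pass. The largest rise was that of SLCO4C1, an organic anion transporter, at 3.19-fold (SE 0.28, adjusted p = 0.0156).

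IER3, an early response gene, was 2.23-fold lower, FST, the activin antagonist follistatin, 2.17-fold, the membrane glycoprotein HAVCR1 2.16-fold, FXYD3, a regulator of the sodium pump, 2.09-fold and the lipocalin LCN15 2.03-fold. ERP27, a protein of the endoplasmic reticulum, was 2.28-fold higher, NPNT, the matrix protein nephronectin, 2.04-fold, and BEX1 1.95-fold. ODAM was 1.95-fold higher, SULT1C2 1.92-fold and DIO1, a deiodinase that activates thyroid hormone, 1.80-fold. TSPAN7 was 1.74-fold higher, SMIM24 1.66-fold, SPTSSB 1.64-fold, the manganese transporter SLC30A10 1.63-fold and the glucuronosyltransferase UGT2A3 1.61-fold. The adjusted p of these genes lay between 0.000206 for ODAM and 0.0247 for SLC30A10. In all, 145 genes were called, 88 higher and 57 lower, and of those at least 2-fold changed 3 were higher and 12 lower. The split was 141 higher and 263 lower after quantile normalization and 34 higher and 38 lower after centring each array on its median. Without the 3 arrays with a raised floor 37 genes were called, 14 higher and 23 lower. Leaving out single arrays gave from 61 genes without wild type replicate 4 to 219 without wild type replicate 3.

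In HIF-2α knockdown 11 lists were shifted by camera, and none of these calls held with an estimated correlation (adjusted p from 0.343 to 0.883). Of the 42 hypoxia-induced HIF targets, 38 were negative, 6 fell, none rose and 36 did not pass, with 12 falls when adjusted over the list alone (median -0.17, camera adjusted p = 1.34e-12; adjusted p = 0.343 with an estimated correlation). Besides NDRG1, BHLHE40 and LOX these were CITED2, a transcriptional cofactor that competes with HIF for its coactivator (log2 fold change -0.54, SE 0.10), SLC2A1, a glucose transporter (-0.60, SE 0.11), and HK2 (-0.46, SE 0.08). After quantile normalization 9 of the targets fell, against 6 in HIF-1α knockdown, and without the raised-floor arrays 1 fell, against 0. In that last fit, with 2 wild type arrays, the medians against wild type were -0.21 in both knockdowns. A larger median shift in HIF-2α knockdown was not seen there, and the direct comparison had a median of -0.04 (camera adjusted p = 0.137). With all arrays the list means differed from wild type by -0.24 in HIF-2α knockdown (exact permutation p = 0.0286). In HIF-1α knockdown they differed by -0.13 (exact permutation p = 0.0571). In the glycolysis list 21 of 22 members were negative and SLC2A3 (-0.90, SE 0.14), SLC2A1, HK2 and the aldolase ALDOA (-0.38, SE 0.07) fell, with 8 falls and 1 rise when adjusted over the list alone (camera adjusted p = 1.22e-08; adjusted p = 0.343 with an estimated correlation). Here 6 fell after quantile normalization and 0 without the raised-floor arrays, where the median was -0.35 (camera adjusted p = 7.65e-09).

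**Figure D2:**
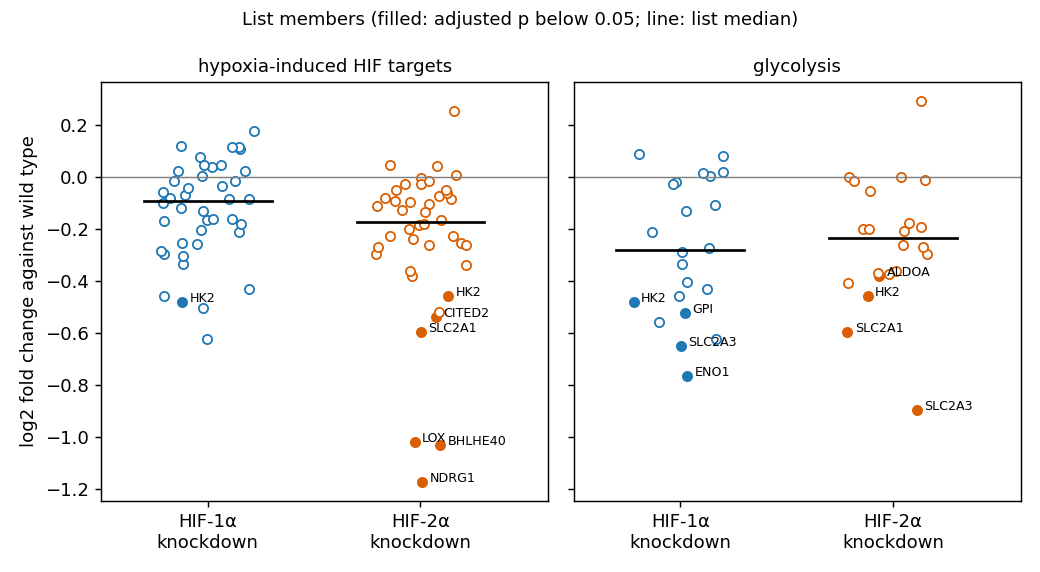
Log2 fold change against wild type of each measured member of the hypoxia-induced HIF targets (42 genes) and of the glycolysis list (22 genes) in each knockdown; filled points passed adjusted p below 0.05 and horizontal lines are list medians. The medians are -0.09 and -0.17 for the hypoxia-induced targets and -0.28 and -0.24 for glycolysis, in HIF-1α and HIF-2α knockdown in that order.

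The extracellular matrix list was lower in HIF-2α knockdown, with LOX the 1 of 37 members that fell and 5 falling when adjusted over the list alone (camera adjusted p = 0.000352; adjusted p = 0.343 with an estimated correlation). Immediate early genes, fixed as a marker of handling, were lower, with IER3 the 1 of 28 that fell and 3 adjusted over the list alone (camera adjusted p = 0.000332; adjusted p = 0.343 with an estimated correlation). The antioxidant list was lower, with GPX3, a secreted glutathione peroxidase, falling by 0.90 (SE 0.17) as the 1 of 39 and 3 adjusted over the list alone (camera adjusted p = 0.000831; adjusted p = 0.771 with an estimated correlation). The Notch list was lower, with MAML2, a Notch coactivator, falling by 0.77 (SE 0.12) as the 1 of 24 and 4 adjusted over the list alone (camera adjusted p = 0.00127; adjusted p = 0.559 with an estimated correlation). Among 32 angiogenic factors CCN2, a matricellular growth factor, fell by 0.67 (SE 0.11), alone also when adjusted over the list alone (camera adjusted p = 0.0037; adjusted p = 0.512 with an estimated correlation, and 0.0502 after quantile normalization). Quantile normalization raised the falls to 5 in the extracellular matrix, 4 in the immediate early, 6 in the antioxidant, 4 in the Notch and 2 in the angiogenic list. It moved the median of the immediate early list from -0.07 to -0.10 and that of the angiogenic list from -0.04 to -0.02. On the deposited values the array means of the antioxidant list gave an exact permutation p of 0.229. Those of the extracellular matrix, immediate early, Notch and angiogenic lists each gave 0.0286, not adjusted for the number of lists. Without the raised-floor arrays 1 immediate early gene fell, and 0 genes of the other 4 lists. Camera then still called the extracellular matrix (median -0.11 against -0.06, adjusted p = 0.000151), antioxidant (-0.20 against -0.11, adjusted p = 2.03e-05), Notch (-0.08 against -0.05, adjusted p = 0.00298) and immediate early lists (-0.06 against -0.07, adjusted p = 0.000404).

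In 4 further lists shifted in HIF-2α knockdown no member passed, also adjusted over the list alone. DNA replication genes were higher, with 31 of 37 positive and a median of 0.10 (camera adjusted p = 0.000332; adjusted p = 0.745 with an estimated correlation). In HIF-2α knockdown replicate 2 the mean of this list lay 0.244 above that of the other 3 arrays, and the exact permutation p of the array means was 0.2. Mitotic genes were higher, with 31 of 38 positive and a median of 0.13 (camera adjusted p = 0.00445; adjusted p = 0.771 with an estimated correlation, and 0.0974 after quantile normalization). Macrophage and leukocyte markers, a check for another cell type, had 15 of 17 members negative and a median of -0.06 (camera adjusted p = 0.0105; adjusted p = 0.698 with an estimated correlation, and 0.0613 after quantile normalization). Ribosomal protein genes had a median of -0.09 (camera adjusted p = 0.0453; adjusted p = 0.883 with an estimated correlation, and 0.113 after centring each array), with array means of 11.73 to 12.27 in HIF-2α knockdown against 11.90 to 12.44 in wild type. Without the 3 arrays with a raised floor the camera adjusted p was 0.122 for DNA replication (median 0.08), 0.161 for mitotic genes (0.115), 0.562 for the macrophage markers (-0.01) and 0.122 for the angiogenic factors (-0.03). The ribosomal protein list then had a median of -0.27 (camera adjusted p = 5.26e-07). That fit keeps wild type replicate 3, at 12.44, and leaves out HIF-2α knockdown replicate 4, at 12.27. After quantile normalization the medians were 0.03 for DNA replication (camera adjusted p = 0.023), 0.05 for mitotic genes and -0.04 for ribosomal protein genes. On the deposited values the array means gave an exact permutation p of 0.371 for mitotic genes, 0.0857 for the macrophage markers and 0.629 for ribosomal protein genes.

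The direct comparison of the knockdowns gave the most calls, 509 genes, with 178 higher in HIF-2α knockdown and 331 lower. The fibrinogen genes were higher in HIF-2α knockdown: FGB 5.22-fold (log2 fold change 2.38, SE 0.11, adjusted p = 1.66e-07), FGA 2.93-fold (SE 0.12, adjusted p = 1.68e-05) and FGG 2.42-fold (SE 0.12, adjusted p = 0.000107). SPTSSB was 3.07-fold higher (SE 0.09, adjusted p = 7.23e-07) and CDO1, the cysteine dioxygenase of taurine synthesis, 2.70-fold higher (SE 0.16). IGFBP1 was 4.74-fold lower in HIF-2α than in HIF-1α knockdown (SE 0.27, adjusted p = 0.000518), CP 2.86-fold lower (SE 0.18) and GDF15, a stress-responsive member of the TGF-β family, 2.20-fold lower (SE 0.10, adjusted p = 3.66e-05).

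HIF1A was 2.78-fold higher and EPAS1 2.13-fold lower in HIF-2α knockdown than in HIF-1α knockdown. SLCO4C1 was 2.54-fold higher, LRRTM4 2.47-fold, ALCAM 2.28-fold, ODAM 2.23-fold, DIO1 1.98-fold and MEP1A, a subunit of the metalloprotease meprin, 1.95-fold. H2BC12 was 2.91-fold lower, ANKRD1, an ankyrin repeat protein, 2.88-fold, FST 2.79-fold, CHST15 2.77-fold, and MXRA7 2.41-fold. IER3 was 2.36-fold lower, the flavin monooxygenase FMO5 2.33-fold, FADS2 2.23-fold and the vitamin D hydroxylase CYP24A1 2.19-fold. The adjusted p of these genes lay between 6.59e-06 for LRRTM4 and 0.0206 for SLCO4C1. Leaving out single arrays gave from 211 genes without HIF-1α knockdown replicate 3 to 618 without HIF-2α knockdown replicate 1. There were 259 genes called without the 3 arrays with a raised floor.

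Between the knockdowns 9 lists were shifted by camera, none with an estimated correlation (adjusted p from 0.640 to 0.711). The extracellular matrix list was lower in HIF-2α knockdown, with 9 of 37 members falling, none rising, and 9 also when adjusted over the list alone (camera adjusted p = 9.69e-05; adjusted p = 0.640 with an estimated correlation). The test fry, which asks whether a list differs from no change and not from other genes, gave an adjusted p of 0.0234. Examples were NID1, a basement membrane protein (log2 fold change -0.59, SE 0.06), the protease inhibitors TIMP3 (-0.48, SE 0.07) and TIMP2 (-0.48, SE 0.08), and LOXL4, a lysyl oxidase (-0.33, SE 0.06). Against wild type the median of the matrix list was 0.03 in HIF-1α knockdown, which camera did not call, and -0.06 in HIF-2α knockdown. The difference between the knockdowns thus need not come from falls in HIF-2α knockdown alone. Immediate early genes were lower, with IER3, the RNA-binding protein ZFP36 (-0.36, SE 0.07) and the transcription factor EGR1 (-0.29, SE 0.07) falling among 28, and 6 falls adjusted over the list alone (camera adjusted p = 0.000278; adjusted p = 0.711 with an estimated correlation; fry adjusted p = 0.0335, against no change). Immediate early genes that fell numbered 5 after quantile normalization and 1 without the raised-floor arrays, where the list median was -0.06 (camera adjusted p = 0.000418). Of the hypoxia-induced targets BHLHE40 (-0.96, SE 0.13), NDRG1 (-0.71, SE 0.12), CITED2 (-0.53, SE 0.10) and LOX (-0.76, SE 0.17) were lower in HIF-2α knockdown, and 6 adjusted over the list alone (camera adjusted p = 0.0407; adjusted p = 0.711 with an estimated correlation, and 0.137 without the 3 arrays with a raised floor). The falls numbered 7 after quantile normalization and 2 without those arrays, and for the extracellular matrix list 10 and 4. The medians without those arrays were -0.04 for the targets, against -0.06 with them, and -0.07 for the matrix list, against -0.08, which camera still called (adjusted p = 0.000283). The glycolysis list did not differ by camera (adjusted p = 0.45), and PFKP, a phosphofructokinase, was the 1 member that fell, with 2 adjusted over the list alone. With all arrays, the array means gave an exact permutation p of 0.0857 for the hypoxia-induced targets. For the matrix and the immediate early list it was 0.0286, not adjusted for the number of lists.

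Hepatocyte secreted proteins were higher in HIF-2α than in HIF-1α knockdown, with the 3 fibrinogen genes and the haem-binding protein HPX (0.39, SE 0.09) rising, IGFBP1 falling, and 5 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.000368; adjusted p = 0.711 with an estimated correlation, and 0.168 after quantile normalization, where the median was 0.03 against 0.10). Stress response genes were lower by a median of 0.10, although GDF15 fell and VLDLR, a lipoprotein receptor, rose (0.47, SE 0.07), with 4 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.0201; adjusted p = 0.711 with an estimated correlation). Of the p53 targets GDF15 and TNFRSF10B (-0.34, SE 0.06) fell, and 4 adjusted over the list alone (camera adjusted p = 0.0237; adjusted p = 0.711 with an estimated correlation, 0.0894 after quantile normalization and 0.234 without the 3 arrays with a raised floor). DNA replication genes were higher, with 32 of 37 positive and no member passing, also adjusted over the list alone (camera adjusted p = 1.09e-06; adjusted p = 0.711 with an estimated correlation). After quantile normalization 5 of them rose. The array means of this list gave an exact permutation p of 0.0286, the smallest possible and not adjusted for the number of lists. The HIF-2α knockdown arrays include the same replicate 2 as above, 0.244 over the other arrays of its group. Ribosomal protein genes were higher with RPL11 rising, also as the 1 adjusted over the list alone (camera adjusted p = 4.81e-14). Histone genes were higher with H2BC3 rising and H2BC12 falling, and 4 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.000121). The ribosomal median was 0.30, and 0.15 after quantile normalization (camera adjusted p = 0.000122). Both lists had an adjusted p of 0.711 with an estimated correlation. The exact permutation p of the array means was 0.0571 for ribosomal protein genes and 0.114 for histone genes. It was 0.2 for secreted proteins, 0.0857 for stress response genes and 0.0571 for p53 targets.

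Against wild type, 14 genes changed in the same direction in both knockdowns and 8 in opposite directions. The 14 became 31 after quantile normalization, 5 after centring and 2 with the ribosomal protein level as covariate. With 1 array left out they ranged from 2, without wild type replicate 4, to 42, without wild type replicate 3. Lower in both were HK2, SLC2A3 and GATM, the first enzyme of creatine synthesis, with log2 fold changes of -0.44 in both knockdowns for GATM. The 11 genes higher in both included TACC1, TSPAN7, SULT1C2, GALNT13, a glycosyltransferase, RHOBTB1 and MCUR1, a regulator of mitochondrial calcium uptake. FGB, FGG, SPTSSB, CARMIL1, CUBN, PROM1 and PLEKHH2 were lower in HIF-1α and higher in HIF-2α knockdown. FGB stood at -1.75 and 0.63, PROM1, a stem cell surface marker, at -0.39 and 0.48, and CUBN, an endocytic receptor, at -0.26 and 0.36. SERPINE2, a protease inhibitor, was the 1 gene higher in HIF-1α knockdown (0.42) and lower in HIF-2α knockdown (-0.45).

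Both comparisons share the wild type arrays, so their chance values are shared too. Simulated unchanged groups against shared controls gave a mean of 0.01 shared genes and at most 1 in 100 simulations. The simulation holds independent noise and no changed gene, so hardly any call could arise in it. It therefore does not measure what shared controls can give in the real arrays, where drawn regroupings shared up to 10 genes. Independent lists of these sizes would share 0.717 genes higher, 0.0836 lower and 0.594 in opposite directions. Fold changes correlated across genes, which are not independent replicates, at r = 0.388 against 0.5 in the simulation, with a covariance of 0.00741 against 0.00371, a difference of 0.0037. With the wild type arrays split between the comparisons in each of 6 ways, r lay between -0.0573 and 0.236, 0 to 3 genes were shared in the same direction and 0 to 4 in opposite directions.

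**Figure D3:**
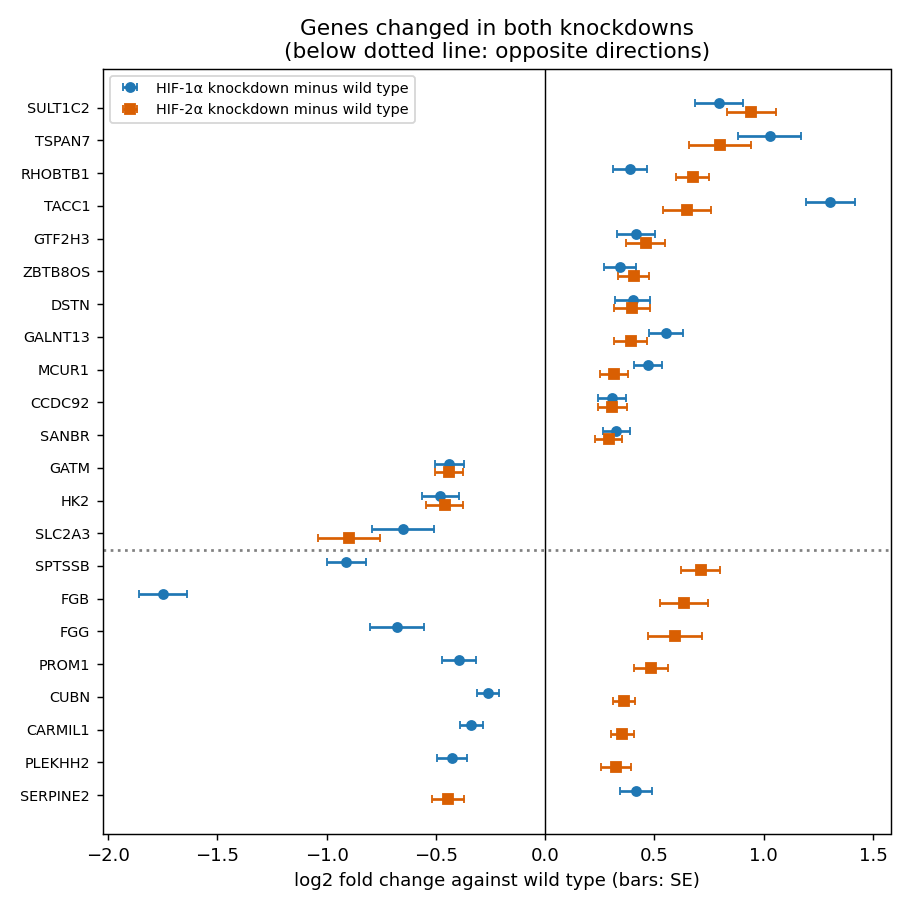
Log2 fold change against wild type, with SE, of the 22 genes called in both knockdowns (circles, HIF-1α knockdown; squares, HIF-2α knockdown). The 14 genes above the dotted line changed in the same direction and the 8 below it in opposite directions, with FGB at -1.75 and 0.63.

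The other 23 lists were called in no comparison, with a lowest camera adjusted p of 0.0686 on the deposited values. With other settings some passed. After quantile normalization drug and hormone metabolism (adjusted p = 0.0406) and heat shock (0.0375) were higher in HIF-1α knockdown, gluconeogenesis and glycogen lower in HIF-2α knockdown (0.023), and fatty acid oxidation higher in HIF-2α than in HIF-1α knockdown (0.0285). Without the raised-floor arrays gluconeogenesis and glycogen were lower in HIF-1α (0.0193) and HIF-2α knockdown (0.0115) against wild type. Between the knockdowns fatty acid oxidation was then higher and the endothelial markers lower in HIF-2α knockdown (both 0.0492). The 23 lists covered HIF and oxygen-sensing components, genes reported to prefer HIF-2α, epithelial and mesenchymal markers, hepatic transcription factors, and drug and hormone metabolism. Metabolic lists among them were bile acids, cholesterol synthesis, fatty acid synthesis and storage, fatty acid oxidation, iron, gluconeogenesis and glycogen, and amino acid and urea metabolism. The others were autophagy, cyclins and their inhibitors, apoptosis, heat shock, interferon, inflammation, Wnt, TGF-β and BMP targets, stem and progenitor markers, and the fibroblast and endothelial markers fixed as checks for other cell types. Lists called on the deposited values also passed in further comparisons with these settings. After quantile normalization DNA replication was lower in HIF-1α knockdown (adjusted p = 0.0075), stress response and oxidative phosphorylation lower in HIF-2α knockdown (0.00817 and 0.0414), and the antioxidant list lower in HIF-2α than in HIF-1α knockdown (0.000253). Without the raised-floor arrays the same 4 passed (0.00693, 0.00712, 4.28e-06 and 0.0492), as did the antioxidant list in HIF-1α knockdown (lower, 0.0227) and the angiogenic factors between the knockdowns (lower in HIF-2α knockdown, 0.0492). On the deposited values every list named here as passing only with other settings had an adjusted p between 0.711 and 0.918 with an estimated correlation, which was not run with those settings. The exact permutation p of their array means was lowest, at 0.0286, for endothelial markers and angiogenic factors between the knockdowns. It was highest, at 0.8, for DNA replication in HIF-1α and oxidative phosphorylation in HIF-2α knockdown. Of the fibroblast and stellate markers PDGFRB, a growth factor receptor, fell in HIF-2α knockdown against wild type (log2 fold change -0.40, SE 0.06, adjusted p = 0.011).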

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

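The tests of scaling and of the fibrinogen genes were chosen only after the result was seen, and the fit without 3 arrays was added after the levels of the arrays were seen. In HIF-1α knockdown against wild type 84.7% of the called genes were higher. After quantile normalization the share was 55.1%, and without the 3 arrays with a raised floor, of which 2 are wild type, it was 36.4% of 22 called genes. Quantile normalization changed the higher calls from 150 to 140 and the lower calls from 27 to 114, so the share moved mainly through added falls. With each array centred on its median the share was 78.8% of 85 called genes. The imbalance thus depends on the kind of processing, and its source is left open.

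By camera the glycolysis list was lower in both knockdowns against wild type, with 4 of 22 genes passing in each (adjusted p = 0.765 and 0.343 with an estimated correlation) and 0 without the raised-floor arrays, where the medians were -0.37 and -0.35 against -0.28 and -0.24 (-0.175 and -0.225 after quantile normalization). A loss of HIF activity, lower values of abundant genes or differences between arrays could each give this. Of 10000 random lists matched on mean expression 0% had a median as low as that of the list in HIF-1α knockdown, and 0% in HIF-2α knockdown, values a general fall of abundant genes would not give, although random lists treat genes as independent. The mean of the list per array gave an exact permutation p of 0.0286 in HIF-1α knockdown, the smallest possible, and of 0.0571 in HIF-2α knockdown. These p-values are not adjusted for the number of lists. In HIF-2α knockdown the genes reported to prefer HIF-2α, a list camera did not call, also reached 0.0286. Differences between arrays unrelated to the knockdown were therefore excluded in neither comparison. The source remains open, since ribosomal protein genes were also lower in HIF-1α knockdown by a median of 0.43 (0.198 after quantile normalization), against 0.152 for matched lists, with 0% of those as low.

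FGB and FGG changed in opposite directions in the knockdowns, while FGA fell in HIF-1α knockdown and was not called in HIF-2α knockdown against wild type (0.34, SE 0.12, adjusted p = 0.243). The median difference of the 3 genes between the knockdowns was 1.55. The other acute phase plasma proteins had a median difference of -0.00775 (mean -0.0149, SE of the mean 0.0891) and the other hepatocyte secreted proteins of 0.0817 (mean 0.0312, SE of the mean 0.0638). A change shared by all members of either group would have moved these genes too, but a change of only some members need not. The SE is taken over genes, which are not independent replicates. The labels give 1 group of arrays per targeted gene, so a difference between the cell populations other than the targeted gene cannot be told apart from an effect of the knockdown.

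For the counts of changed genes the real grouping stood alone, which is the smallest share that so few splits can give. Splits that mix differing groups widen the spread within groups and so call few genes, so they do not fully exclude chance. Of the 35 splits of 8 arrays 1, the real grouping, reached the count in each comparison. The highest other counts were 0 for HIF-1α knockdown against wild type, 17 for HIF-2α knockdown against wild type and 0 between the knockdowns. For the 14 shared genes 1 of 100 drawn splits, the real grouping, reached the count, and the highest other was 10. The draws also use the same wild type arrays for both comparisons. With these arrays split between the comparisons, which leaves fewer in each, 0 to 3 genes were shared. For the number of shifted lists chance cannot be excluded: 17, 14 and 16 of 35 splits gave as many, with the highest other counts at 18, 20 and 18 against 7, 11 and 9.

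For 8 genes called in both knockdowns in opposite directions, the direct test between the knockdowns gave differences of 2.38 for FGB, 1.62 for SPTSSB, 1.27 for FGG, 0.878 for PROM1, 0.751 for PLEKHH2, 0.691 for CARMIL1, 0.622 for CUBN and -0.861 for SERPINE2. Since the genes were picked for opposite changes, these differences follow from the selection and are no separate evidence.

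In 20 of 384 groups of arrays, 3 for each of 128 genes that are named or are called members of a list, 1 array lay far from the other 3 by Dixon's test, and chance gives about 5%. Relative to the mean of the other 3 arrays these were, in wild type replicate 3, FST at 0.925, WIPI1 at 0.745 and ADH6 at 0.529. They were also, in wild type replicate 2, H2BC3 at -0.62 and SERPINH1 at -0.285; in wild type replicate 1, ICAM1 at -0.376; and in wild type replicate 4, PFKP at 0.256 and MCUR1 at -0.102. In HIF-1α knockdown replicate 3 they were GDF15 at 0.438, CCN2 at 0.341, NDRG1 at 0.24, TNFAIP3 at 0.143, ALCAM at -0.252 and ERP27 at -0.227, with SLC40A1 at -0.266 in replicate 1 and TNFRSF10B at -0.194 in replicate 4. In HIF-2α knockdown replicate 2 they were RHOBTB1 at 0.351, IFIH1 at 0.21, CYP4F2 at -0.29 and FADS2 at -0.256. The mean of the DNA replication list lay apart in HIF-2α knockdown replicate 2, at 0.244, and that of the histone list in replicate 1, at -0.239.

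Among 13163 probe sets without a single gene name, which no comparison above uses, limma called 52 in HIF-1α knockdown against wild type, 39 in HIF-2α knockdown against wild type and 62 between the knockdowns. These are 0.395%, 0.296% and 0.471% of them, against 0.621%, 0.522% and 1.89% of the probe sets with a single gene.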

How the results depend on the processing

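The fits without the 3 arrays with a raised floor and with the ribosomal protein level as covariate were chosen only after the result was seen. Of 2079 results of called named genes under 11 alternatives, 1743 stayed past the threshold, 336 did not and 0 reversed. Of 2268 with 1 array left out 443 did not stay past it and 0 reversed. The groups of nearly all called genes do not overlap, so leaving out 1 array could hardly reverse a sign. Some alternatives change only the estimate of the spread and cannot reverse one. The absence of reversals is therefore no separate evidence. The 2268 results include fits that leave out an array of the group not compared. Among the called results, 103 of 189 passed in every fit with 1 array left out. Of the 189 calls behind these results, 117 were lost without the raised-floor arrays, 69 with the ribosomal covariate and 62 with centring, against 0 to 31 with each other alternative. The fall of EPAS1 in HIF-2α knockdown passed under every alternative.

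In HIF-1α knockdown against wild type the 177 changed genes became 85 with each array centred, 396 with only the 2 groups compared, 288 with trend and robust eBayes, 605 with array weights, 22 without the raised-floor arrays and 22 with the ribosomal covariate. In HIF-2α knockdown against wild type the 145 became 404 after quantile normalization, 72 centred, 64 with only the 2 groups, 285 with trend and robust eBayes and 37 without the raised-floor arrays. Between the knockdowns the 509 became 888 after quantile normalization, 337 centred, 980 with array weights, 259 without the raised-floor arrays and 250 with the ribosomal covariate. The 14 shared genes became 31, 5, 9, 23, 6 and 2 with quantile normalization, centring, only 2 groups, trend and robust eBayes, no raised-floor arrays and the ribosomal covariate. With at least 1.5-fold required, 42, 50, 115 and 4 remained in that order, and with adjusted p below 0.01, 37, 34, 165 and 2, by construction; for the other changes the cause was not tested.

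Leaving out 1 array gave 50 to 483, 61 to 219 and 211 to 618 changed genes and 2 to 42 shared genes. HIF1A in HIF-1α knockdown was at -1.24 (adjusted p = 0.103) without the raised-floor arrays, which leaves fewer arrays, and at -1.05 (adjusted p = 0.0807) with the ribosomal covariate. EPAS1 in HIF-1α knockdown, not called at -0.03, was at 0.11 with that covariate and between -0.086 and 0.055 with 1 array left out. Shifted lists numbered 0, 0 and 0 with an estimated correlation and in HIF-1α knockdown 4 to 8 with 1 array left out. The test fry, which asks another question, whether a list differs from no change, called 0, 0 and 2 lists.

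The arrays share replicate numbers, which the labels do not describe as pairs. Of 12 same-number pairs 5 had deviations that correlated above 0.1 (r from -0.171 to 0.637), and 3 of 12 arrays correlated best with their own number. Between wild type and HIF-1α knockdown r was 0.17, 0.306, 0.637 and -0.0393 for replicates 1 to 4. Between wild type and HIF-2α knockdown it was negative throughout (-0.171 to -0.0266), and between the knockdowns 0.0278 to 0.217. A pairing of wild type with HIF-1α knockdown arrays can thus not be excluded. With a replicate block 234, 202 and 562 genes were called, 20 were shared, and 7, 11 and 9 lists were shifted.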

Other observations

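The lists were fixed before the data were examined, and only the counts without the raised-floor arrays come from a fit chosen after the arrays were seen. Of the drug and hormone metabolism genes 8 fell and 1 rose in HIF-2α against HIF-1α knockdown, although camera did not call the list (adjusted p = 0.389; 0.768 with an estimated correlation). ABCG2, an efflux transporter, was lower by 0.78 (SE 0.13), and CYP19A1, the aromatase, by 0.83 (SE 0.10). Against wild type ABCB4, the phospholipid transporter of bile, was higher in HIF-1α knockdown by 0.53 (SE 0.06), SLC51B, a bile acid transporter, by 0.78 (SE 0.12) and SULT2A1, a sulfotransferase of steroids and bile acids, by 0.57 (SE 0.09). AKR1D1, a reductase of bile acid synthesis, was higher in HIF-2α knockdown by 0.45 (SE 0.09).

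In the Notch list 4 genes were lower in HIF-2α than in HIF-1α knockdown: HEY1 by 0.81 (SE 0.12), MAML2 by 0.62 (SE 0.12), JAG1 by 0.45 (SE 0.09) and HES1 by 0.43 (SE 0.09). Camera did not call this list (adjusted p = 0.0584; 0.711 with an estimated correlation), and 1 of its genes fell without the raised-floor arrays, where the median was -0.05 against -0.06. In the iron list SLC40A1, the iron exporter, was lower by 0.72 (SE 0.13), while STEAP2, a metalloreductase, was higher in HIF-2α knockdown than in wild type by 0.41 (SE 0.07). Of the stem and progenitor markers CD24 was lower in HIF-2α knockdown than in wild type by 0.63 (SE 0.13), and LIN28B was higher in HIF-1α knockdown by 0.54 (SE 0.10). Among stress response genes NUPR1 was higher in HIF-1α knockdown by 0.61 (SE 0.08).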
